A study of Mus musculus with 6 samples.

How the data were processed

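RNA was measured by sequencing in 6 libraries from CD3+ T cells purified from the spleens of C57BL/6 mice that had received a graft, 3 from isograft recipients (graft from a genetically identical donor) and 3 from allograft recipients (graft from a genetically different donor). CD3 is the signalling part of the T cell receptor complex and marks T cells. Per the labels' protocols, the cells were kept in culture medium with serum, RNA was extracted with TRIzol, and libraries were made with a SMARTER mRNA kit. The grafted organ, the donor strain, the time after grafting and the length of the culture are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical in part.

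Per the file headers, the authors counted fragments of read pairs over exons with featureCounts 1.6.0, summed per Ensembl gene, after an alignment with HISAT, whose version is not given in the sources used here. The deposited values are whole-number counts per gene with no normalization. The recorded command sets no strand option and no option for multi-mapped reads, so by that tool's defaults reads from a gene and its antisense partner are not told apart, and reads that map to several places are left out. Genes with near-identical copies or processed pseudogenes are therefore undercounted, among them Gapdh, at 14 to 29 CPM (the count divided by the library total and put on the usual common scale), and mitochondrial genes with nuclear copies. The headers name the Ensembl annotation release 104 on GRCm39, while the submitters' processing notes name GRCm38 and mm10. Of 52096 genes on the same chromosome in the headers' annotation and in a GRCm38 annotation, 46545 have intervals that do not overlap between them, and these genes hold 84.38% of the counts. Of 20 T cell identity genes, 16 do not overlap, and the lowest total of those 16 was 8743 counts, which alignments to the other build would not give. Coordinates are printed from the files, as GRCm39. Gene symbols were matched by Ensembl ID for 52083 of 55416 genes (93.99%).

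Library totals ran from 30066137 to 37821738 counts. Genes were kept by edgeR's filterByExpr with the group, which left 14926 genes holding 99.92% of the counts. Libraries were scaled by TMM (trimmed mean of M values), and edgeR's quasi-likelihood test with robust estimation compared allograft with isograft libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is allograft minus isograft, and its SE is the size of the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 libraries per group. Before the data were examined, 34 gene lists were fixed, of which 32 had at least 5 members past the filter. Lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. The megakaryocyte and platelet list (3 members past the filter) and the stromal and endothelial list (4 members) were not tested.

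The named genes follow a rule also set before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes past the threshold with at least 5 CPM in the higher group, no overlap between groups and no predicted or clone name. It adds up to 3 members of each list with the smallest p, and 18 genes of T cell function whatever their result. Some genes that the rule takes are not reported here. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3 and matplotlib 3.10.9.

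Simulated counts for the same 14926 genes and library sizes were used to test the procedure on known answers. edgeR called 74.6% of 67 genes changed 1.5-fold, 89.6% of 67 genes changed 2-fold, and 0.0612% of 14701 unchanged genes. Changed genes had a mean of at least 1 CPM and were few, unlike in the real comparison, so these rates may not hold there. In the list test the 1 shifted list was called and 0 of 30 unshifted lists were. Simulated genes were drawn independently of one another, so this cannot show how the test treats lists of correlated genes. Libraries were compared before they were averaged: within a group the chi-square per degree of freedom ran from 10.2 to 21.7, above sampling noise, so no pair looked like 1 library used again.

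The alternatives were RLE scaling, total counts without scaling factors, DESeq2, limma-voom, non-robust estimation, no low-count filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, each of the 6 libraries left out, immunoglobulin, hemoglobin and mitochondrial genes left out, and an offset removing a smooth trend of gene length and GC content per library (GC known for 99.591% of genes tested). List tests were also run with the estimated correlation and a prior count of 0.5.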

Results

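Gene expression was measured in CD3+ T cell fractions from the spleens of C57BL/6 mice, in 3 libraries from isograft recipients and 3 from allograft recipients. Totals were 30066137, 37821738 and 30117202 counts in isograft replicates 1, 2 and 3, and 34123777, 31298109 and 30078504 in allograft replicates 1, 2 and 3. The comparison asks how expression in the spleen T cell fraction of allograft recipients differs from that of isograft recipients. The leading principal component held 73.8% of the variance and separated the groups, and log2 levels correlated across genes at 0.986 to 0.990 within groups and 0.946 to 0.952 between them.

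Allograft libraries had higher levels of genes of lymphocyte activation and costimulation and lower levels of genes of naive, resting T cells. In the activation and costimulation list 23 of 24 members rose (camera adjusted p = 8.0e-12, and adjusted p = 0.13 with an estimated correlation). In the naive and quiescent list 16 of 20 fell (camera adjusted p = 2.4e-05, and adjusted p = 0.22 with an estimated correlation). In the B cell list 11 of 20 members fell and 4 rose. That list did not pass (camera adjusted p = 0.052, and adjusted p = 0.33 with an estimated correlation). Lif, a cytokine of the interleukin 6 family (chromosome 11, 4207557 to 4222514, GRCm39), rose from 1.78 ± 0.556 to 113.5 ± 15.2 CPM (SD, n = 3), a log2 fold change of 6.01 ± 0.17 (SE). Tnfsf14, a costimulatory ligand of the TNF family (chromosome 17, 57496492 to 57501177), rose by 4.86 ± 0.14, and the chemokine gene Xcl1 by 4.77 ± 0.17. Il2ra, the interleukin 2 receptor alpha chain (chromosome 2, 11647618 to 11698004), rose from 41.8 ± 2.96 to 536.6 ± 33.2 CPM. Lef1, a transcription factor of naive T cells (chromosome 3, 130904120 to 131018005), went from 339.6 ± 34.7 to 79.6 ± 9.23 CPM, a log2 fold change of -2.09 ± 0.09.

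By edgeR's quasi-likelihood test 4283 genes rose and 4349 fell out of 14926 tested, 57.8% of the genes. Counts of list members that rose or fell are to be read against these shares, which many lists did not clearly exceed. At least 2-fold, 1502 rose and 1501 fell. Groups did not overlap for 63.3% of the genes, against 10% by chance. The balance of rises and falls depends on the scaling: with total counts in place of TMM, the median of all genes moved by -0.22 on the log2 scale and 2973 genes rose while 6093 fell. A filter of at least 5 CPM in 3 libraries, which tests 9638 genes, left 918 rises and 848 falls of at least 2-fold.

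**Figure D1:**
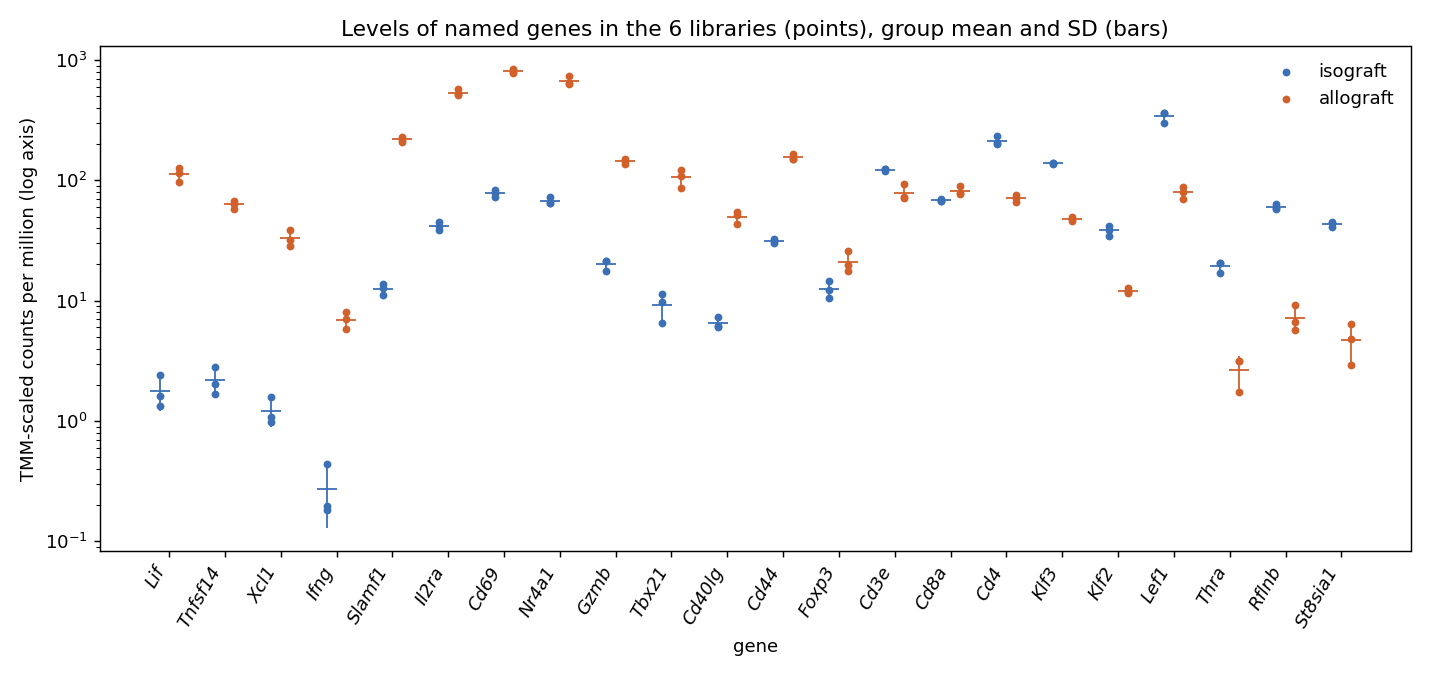
TMM-scaled CPM (log axis) of 22 named genes in each isograft and allograft library, with 3 points per group and bars for the group mean and SD. Lif moved from 1.78 to 113.5 CPM on average, and Lef1 from 339.6 to 79.6.

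The other genes among the 8 largest rises were Il22 (5.53 ± 0.25), Ifng (4.69 ± 0.29), Spry1, an inhibitor of growth factor signalling (4.46 ± 0.16), Tnfsf11, the ligand RANKL (4.15 ± 0.18), and Slamf1, a lymphocyte surface receptor (4.13 ± 0.09). Ifng, the gene of interferon gamma (chromosome 10, 118276951 to 118281797), stayed at low counts, 0.272 ± 0.143 against 6.96 ± 1.14 CPM. Il22 has a near-identical copy in this strain, so its level is uncertain. The largest falls were Gprc5b (-3.47 ± 0.25), Tbxa2r, the thromboxane receptor (-3.37 ± 0.25), Cyp2s1 (-3.30 ± 0.58), St8sia1, a ganglioside sialyltransferase (-3.21 ± 0.20), Rflnb (-3.05 ± 0.13), the amino acid transporter gene Slc6a19 (-2.96 ± 0.54), Thra, a thyroid hormone receptor (-2.86 ± 0.18), and Mturn (-2.78 ± 0.13).

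In the activation and costimulation list, 23 of 24 members rose and 0 fell, with a median log2 fold change of 2.29 (camera adjusted p = 8.0e-12, and adjusted p = 0.13 with an estimated correlation). The early activation antigen Cd69 rose from 78.1 ± 4.80 to 803.5 ± 32.6 CPM, the transcription factor gene Irf4 by 2.58 ± 0.07, and Cd44, an adhesion receptor of activated and memory T cells, by 2.31 ± 0.08. Il2 rose by 3.66 ± 0.42 but reached only 1.97 ± 0.290 CPM, and the member that did not pass was Cd38. Several members, Irf4, Irf8 and Cd83 among them, are also expressed by B cells, whose transcripts were present in every library.

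B-lineage transcripts reached the levels of T cell genes in both groups. Ms4a1, the B cell surface protein CD20, which was chosen after its values were seen, stood at 124.6 ± 4.35 CPM in isograft and 143 ± 2.33 in allograft libraries, against 122.6 ± 2.997 and 79.1 ± 12.5 for Cd3e, the CD3 epsilon chain. The B cell list's members summed to 3686 ± 136.3 CPM in isograft and 3251 ± 83.2 in allograft libraries, and those of the T cell identity list to 2760 ± 62 and 2560 ± 118.4. These levels are not corrected for gene length. In the B cell list 4 of 20 members rose and 11 fell (camera adjusted p = 0.052, and adjusted p = 0.33 with an estimated correlation). Fcer2a, the low-affinity IgE receptor (chromosome 8, 3731737 to 3744175), rose from 52.8 ± 0.951 to 378 ± 22.6 CPM, while Ralgps2 (-1.41 ± 0.08) and Fcrla (-1.35 ± 0.08) fell. The camera call for the B cell list was gained with total counts (adjusted p = 0.037), limma-voom (0.027), no low-count filter (0.014) and the length and GC offset (0.037), and without isograft replicate 2 (0.047) or isograft replicate 3 (0.042).

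The naive and quiescent T cell list had 16 of 20 members that fell and 0 that rose, with a median of -1.08 (camera adjusted p = 2.4e-05, and adjusted p = 0.22 with an estimated correlation). The Kruppel-like factor genes Klf3 and Klf2, the second a regulator of T cell exit from lymphoid tissue, fell by 1.54 and 1.67 on the log2 scale. The fall of Ccr7, a chemokine receptor for lymph node entry, was small (-0.19 ± 0.07) and missed the threshold without isograft replicate 1 (adjusted p = 0.082), isograft replicate 3 (0.077) or allograft replicate 2 (0.13).

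Lineage genes moved apart. In the T cell identity list 6 of 20 members rose and 9 fell (camera adjusted p = 0.44). Cd3e fell by 0.63 ± 0.09, Cd247, the CD3 zeta chain, from 379.2 ± 22.2 to 148.6 ± 4.02 CPM, and Ubash3a, an inhibitor of receptor signalling, by 2.33 ± 0.09, while Cd5 rose by 1.38 ± 0.08. Cd4 (chromosome 6, 124841655 to 124865184) went from 211.4 ± 18.5 to 71.2 ± 4.99 CPM. In the CD4 lineage list 3 of 6 members rose and 1 fell (adjusted p = 0.50), with rises of the CD40 ligand gene Cd40lg (2.95 ± 0.12) and Tnfsf8 (1.87 ± 0.08). In the CD8 lineage list 3 of 6 rose and 2 fell (adjusted p = 0.75). Crtam rose by 3.91 ± 0.12, Cd8b1 fell by 0.55 ± 0.08, and Cd7 was low in both groups (1.19 and 0.229 CPM). Cd8a differed by 0.26 ± 0.08, which did not pass with total counts (0.04, adjusted p = 0.68) or without allograft replicate 1 (0.18, adjusted p = 0.054).

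Of the cytotoxic effector list, 11 of 22 members rose and 3 fell (camera adjusted p = 0.028, and adjusted p = 0.22 with an estimated correlation). Gzmb, the cytotoxic protease granzyme B (chromosome 14, 56496295 to 56499717), rose from 20.02 ± 2.13 to 144.4 ± 7.43 CPM, Prf1, the pore-forming perforin, by 1.53 ± 0.10, and the chemokine genes Ccl3 and Ccl4 by 3.26 ± 0.14 and 2.79 ± 0.14. The list's call was lost without isograft replicate 3 (adjusted p = 0.067), without allograft replicate 1 (0.053) and with the length and GC offset (0.083). The NK cell list did not pass (adjusted p = 0.67), with 2 of 14 members that rose and 1 that fell. Eomes, a transcription factor of NK and CD8 T cells, rose by 1.48 ± 0.12, Cd244a by 0.83 ± 0.20, and Gzma fell by 0.39 ± 0.10.

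Helper T cell lists did not pass as wholes. In the Th1 list 8 of 16 rose and 2 fell (camera adjusted p = 0.085). Tbx21, the Th1 transcription factor T-bet, went from 9.22 ± 2.46 to 106.2 ± 18.2 CPM and Lta from 7.07 ± 0.882 to 61.4 ± 9.68. That list passed without isograft replicate 1 (adjusted p = 0.042) and with total counts (0.040), limma-voom (0.033), no low-count filter (0.017) and the filter of at least 5 CPM (0.034). In the Th2 list 3 of 8 rose and 1 fell (adjusted p = 0.16): Il4ra rose by 0.24 ± 0.07, which total counts ended (adjusted p = 0.79), and Ccr8 and Il5 rose at 1.03 ± 0.121 and 1.27 ± 0.433 CPM in allograft libraries. Gata3, the Th2 transcription factor, fell by 0.78 ± 0.31, a call lost without isograft replicate 1 (adjusted p = 0.084), 2 (0.052) or 3 (0.14) and without allograft replicate 2 (0.072) or 3 (0.11). Its log2 fold change was -0.44 without allograft replicate 3, and -0.67 to -0.87 in the other fits that lost the call. In the Th17 list 4 of 9 rose and 2 fell (adjusted p = 0.54). Csf2, the cytokine GM-CSF, rose by 3.46 ± 0.22, and Ccr6 fell by 0.77 ± 0.10. In the follicular helper list 8 of 13 rose and 3 fell (adjusted p = 0.075, 0.037 with total counts and 0.020 with no low-count filter). Btla rose by 1.65 ± 0.08, Cxcr5 by 1.07 ± 0.07 and Cd200 by 1.43 ± 0.10, and B cells express Btla and Cxcr5 too.

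In the regulatory T cell list 13 of 19 members rose and 3 fell (camera adjusted p = 0.0080, and adjusted p = 0.22 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, went from 12.5 ± 1.95 to 21.2 ± 4.44 CPM (0.76 ± 0.15), Tnfrsf4 rose by 0.89 ± 0.08, Ebi3 by 3.57 ± 0.26 and Il10 by 1.92 ± 0.35. Tgfb1 rose by 0.53 ± 0.10. Il2ra, Tnfrsf4 and Tnfrsf18 are shared with the activation list. The filter of at least 5 CPM ended the list's call (adjusted p = 0.063). In the inhibitory receptor and exhaustion list 13 of 17 rose and 2 fell (camera adjusted p = 0.00067, and adjusted p = 0.17 with an estimated correlation). Pdcd1, the receptor PD-1, rose by 1.62 ± 0.15, and Nr4a1, Nr4a2 and Nr4a3, transcription factors induced by receptor signalling, by 3.31 ± 0.08, 3.26 ± 0.11 and 3.07 ± 0.07.

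Immediate early and heat shock genes rose in 16 of 21 cases and fell in 0 (camera adjusted p = 3.2e-05, and adjusted p = 0.30 with an estimated correlation), Jun by 1.84 ± 0.09, Fosl2 by 1.596 ± 0.08 and Atf3 by 1.93 ± 0.09. In the apoptosis and death receptor list 14 of 23 rose and 1 fell (adjusted p = 0.0018, and adjusted p = 0.17 with an estimated correlation). The members with the smallest p were survival genes: Bcl2l1 rose by 3.42 ± 0.10, Cflar by 1.56 ± 0.07, and Bcl2a1d by 2.71 ± 0.10, the last uncertain because near-identical copies share its reads. In the unfolded protein response list 13 of 22 rose and 3 fell (adjusted p = 0.011, and adjusted p = 0.31 with an estimated correlation), with the chaperone gene Hspa5 up by 1.48 ± 0.07, Atf4 by 1.56 ± 0.08 and Trib3 by 2.78 ± 0.11.

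The glycolysis, oxidative phosphorylation and cholesterol synthesis lists passed upward. In glycolysis 16 of 23 members rose and 4 fell (camera adjusted p = 0.0085, and adjusted p = 0.62 with an estimated correlation), with Ldha at 263.1 ± 36.3 against 651.7 ± 22.3 CPM, Pfkp up by 1.29 ± 0.08 and the lactate transporter gene Slc16a1 by 2.14 ± 0.09. In oxidative phosphorylation 24 of 46 rose and 3 fell (adjusted p = 0.0085, and adjusted p = 0.36 with an estimated correlation), with Cycs up by 1.48 ± 0.09, Atp5b by 0.78 ± 0.07 and Cox7b by 0.69 ± 0.08. Total counts (adjusted p = 0.071) and the length and GC offset (0.099) ended that call. In cholesterol synthesis 14 of 24 rose and 4 fell (adjusted p = 0.0064, and adjusted p = 0.22 with an estimated correlation), with Cyp51 up by 1.42 ± 0.08 and Insig1 by 1.24 ± 0.08. Cytosolic ribosomal protein genes did not pass (adjusted p = 0.070), with 15 of 48 that rose and 2 that fell, Rpl15 by 0.53 ± 0.07, Rps25 by 0.48 ± 0.07 and Rpl14 by 0.45 ± 0.08. Their median of 0.13 became -0.09 with total counts, where 7 rose and 14 fell, and the list passed with no low-count filter (adjusted p = 0.046) and without isograft replicate 1 (0.014) or allograft replicate 2 (0.048). Mitochondrially encoded genes did not pass either (adjusted p = 0.054), with 5 of 13 that rose. With total counts or the length and GC offset 0 of them rose, so the calls of mt-Nd1 (0.60 ± 0.15), mt-Nd5 (0.27 ± 0.09) and mt-Co2 (0.50 ± 0.14) depend on the scaling. The mitochondrial list passed with limma-voom (adjusted p = 0.033) and no low-count filter (0.013), and without isograft replicate 1 (0.031), isograft replicate 2 (0.020) or allograft replicate 3 (0.040). Of the single genes, mt-Nd1 was lost without isograft replicate 1 (adjusted p = 0.055) or allograft replicate 1 (0.091), and mt-Nd5 without isograft replicate 3 (0.11) or allograft replicate 2 (0.072). In those fits the log2 fold change of mt-Nd1 was 0.63 and 0.56, and that of mt-Nd5 was 0.15 and 0.24.

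**Figure D2:**
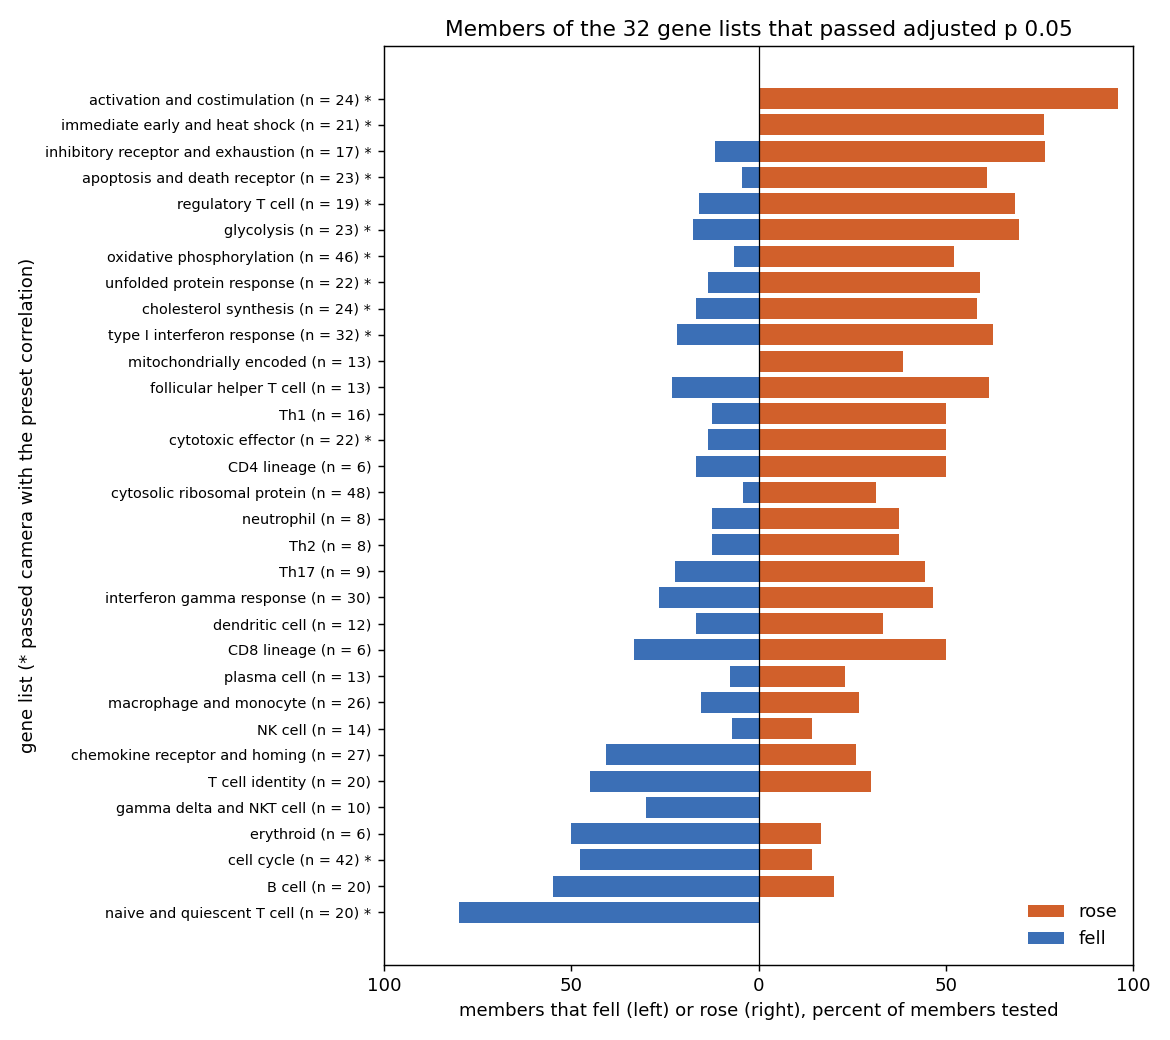
Share of tested members that rose (right) or fell (left) at adjusted p 0.05 in each of 32 gene lists, as a percent of members tested, with an asterisk for the 13 lists that passed camera with the preset correlation. The activation and costimulation list is at the top with 23 of 24 members up, and the naive and quiescent list is at the bottom with 16 of 20 down.

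Cell cycle genes moved in both directions, with 6 of 42 that rose and 20 that fell (camera adjusted p = 0.030, and adjusted p = 0.50 with an estimated correlation). With total counts 3 rose and 31 fell. Tk1, a thymidine kinase, rose by 1.70 ± 0.08 and Pcna, the DNA polymerase clamp, by 0.77 ± 0.07, while Stmn1 fell by 0.73 ± 0.09. Mki67, a gene of cycling cells, differed by -0.08 ± 0.08 (adjusted p = 0.39) and passed with total counts (-0.30, adjusted p = 0.0029) and without allograft replicate 3 (-0.18, adjusted p = 0.044). The list's call was lost without allograft replicate 2 and with the length and GC offset (adjusted p = 0.056 in each). Its median log2 fold change was -0.27 and -0.34 there, against -0.33 in the main test.

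In the type I interferon response list 20 of 32 members rose and 7 fell (camera adjusted p = 0.028, and adjusted p = 0.57 with an estimated correlation), with Isg15 up by 1.595 ± 0.08, Isg20 by 1.66 ± 0.07 and Mx1 by 1.30 ± 0.09. Its call was lost with total counts (adjusted p = 0.085), the filter of at least 5 CPM (0.063), the length and GC offset (0.083) and without allograft replicate 3 (0.059). The list's median of 0.26 became 0.04 with total counts and 0.20 to 0.24 in the other fits that lost the call. The interferon gamma response list did not pass (adjusted p = 0.32), with 14 of 30 that rose and 8 that fell. The chemokine genes Cxcl9 and Cxcl10 rose by 2.51 ± 0.11 and 1.53 ± 0.10, and Gbp5 by 1.03 ± 0.07. Chemokine receptor and homing genes rose in 7 of 27 cases and fell in 11 (adjusted p = 0.44), with Gpr183 up by 1.43 ± 0.08 and S1pr4, a sphingosine phosphate receptor, at 12.3 ± 1.08 against 1.98 ± 0.177 CPM.

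Lists of other cell types did not pass the test. Macrophage and monocyte members rose in 7 and fell in 4 of 26 cases (camera adjusted p = 0.60), with Hmox1 (1.15 ± 0.14) and Axl (0.64 ± 0.11) up and Lyz2 (-0.55 ± 0.08) down. Dendritic cell members rose in 4 and fell in 2 of 12 cases (adjusted p = 0.49), with Zbtb46 up by 2.11 ± 0.09, Ccl22 by 1.46 ± 0.13 and H2-Ab1 by 0.51 ± 0.12. For plasma cells 3 of 13 rose and 1 fell (adjusted p = 0.69), Sdc1 going from 17.7 ± 1.11 to 6.16 ± 0.622 CPM. For neutrophils 3 of 8 rose and 1 fell (adjusted p = 0.82), with a median of -0.16 and a mean of 0.26, and Il1r2 rose by 0.87 ± 0.22. Its members summed to 26.3 ± 7.77 CPM in isograft and 72.4 ± 24.2 in allograft libraries, of which Il1b, an inflammatory cytokine gene, made 12.4 ± 7.48 and 58.4 ± 26.0. For erythroid genes 1 of 6 rose and 3 fell (adjusted p = 0.75), with a median of -0.39 and a mean of 0.15. The transferrin receptor gene Tfrc, which is also in the activation list, rose by 2.26 ± 0.08, and Bpgm fell by 1.10 ± 0.12. Erythroid members summed to 79.8 ± 4.50 and 244.4 ± 18.04 CPM, of which Tfrc made 47.0 ± 3.76 and 224.5 ± 20.5. For gamma delta and NKT cells 0 of 10 rose and 3 fell (adjusted p = 0.45), with Blk, also a B cell gene, at -0.55 ± 0.08 and Cd163l1 at -1.09 ± 0.23.

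With an estimated correlation 0 of the 32 lists passed after adjustment and 7 had an unadjusted p under 0.05. By fry 25 lists had a net direction, but fry does not compare a list with the other genes. Since 57.8% of the genes tested changed, a list can pass fry without standing out from them. Counts of members that rose and fell, adjusted over the list alone, were those over all genes except in 13 lists. They were 12 and 3 for cytotoxic effector, 3 and 0 for Th2, 13 and 4 for regulatory T cell, 17 and 0 for immediate early and heat shock, 21 and 7 for type I interferon and 15 and 8 for interferon gamma. They were 8 and 13 for chemokine receptor and homing, 16 and 5 for cholesterol synthesis, 12 and 2 for ribosomal protein and 13 and 4 for unfolded protein response. They were 0 and 1 for plasma cell, 0 and 2 for gamma delta and NKT cell, and 4 and 0 for mitochondrially encoded genes.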

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

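The direction held for the 122 named genes under every alternative that tested them, and 108 kept their side of the threshold in each. Changed genes numbered 8632, with 8535 by DESeq2, 8683 by limma-voom and 7900 to 8449 with 1 library left out, and no gene called in both a setting and the main test changed sign. Falls of at least 2-fold moved from 1501 to 2267 with total counts. With at least 5 CPM in 3 libraries, changes of at least 2-fold moved from 3003 to 1766, rises from 1502 to 918 and falls from 1501 to 848, because fewer genes were tested. Lists called numbered 13, 12 to 16 with 1 library left out, 18 with no low-count filter, 16 with limma-voom, 14 with total counts, 12 with the filter of at least 5 CPM, 10 with the length and GC offset, and 0 with an estimated correlation.

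List medians that turned sign belonged to lists that passed in neither setting. With total counts these were CD8 lineage (-0.0875), interferon gamma response (-0.12), cytosolic ribosomal protein (-0.0905), macrophage and monocyte (-0.14), dendritic cell (-0.16) and NK cell (-0.0159), which is what the shift of all genes by -0.22 gives. The dendritic cell median also turned with no low-count filter (-0.0578) and ranged from -0.0295 to 0.131 with 1 library left out, below 0 without isograft replicate 3 (-0.0075) or allograft replicate 3; the cause was not tested.

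The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered samples from their group means correlated at -0.063, 0.0029 and -0.034. These values show no strong shared effect but do not exclude pairing. With the replicate number as a block 8216 genes changed, 2927 of them at least 2-fold, and 14 lists passed, the mitochondrially encoded list being the one gained (adjusted p = 0.015). Of the named genes, Ighg1 (adjusted p = 0.076) and Tcrg-C1 (0.089) did not pass with the block. The calls lost most often were those of Ighg1, Tcrg-C1 and Trem1, in 11, 8 and 7 of the alternatives. Their adjusted p in edgeR's main test were 0.0484, 0.0484 and 0.026, so Ighg1 and Tcrg-C1 lay at the threshold. Levels were low for Tcrg-C1 (0.88 CPM in isograft and 0.38 in allograft libraries) and Trem1 (0.22 and 0.61). The cause of the lost calls was not tested further. At this depth and number of libraries, simulated changes of 1.5-fold were called in 74.6% of cases. Few genes changed in that simulation, so the rate may differ in the real comparison.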

Other observations

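The lists in this part and the tests on B-lineage genes were chosen only after results had been seen; the splits, the length and GC tests and the held-out cell cycle test were written before their results were seen.

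Further gene groups are given as counts of edgeR's calls with no list test, since some of their members were chosen because they had been seen to change. All 34 ribosome biogenesis genes rose, with a median log2 fold change of 1.75. Rrp1b rose from 40.8 to 293.9 CPM and Nolc1 from 436.1 to 2186. Of 19 aminoacyl-tRNA synthetase genes 18 rose and 1, Qars, fell (median 1.48), with Tars at 223.1 against 894.9 CPM. The fall of Qars (-0.18) did not pass with RLE scaling, DESeq2 or the length and GC offset. In serine, one-carbon and polyamine metabolism 13 of 15 rose and 0 fell, or 1 with total counts (median 1.79), with Shmt1 and Psat1 up by 2.81 and 2.60 on the log2 scale. Of 16 NF-kB feedback genes 13 rose and 1, Tnip1, fell, and of 14 MAPK and calcium feedback genes 8 rose and 2 fell. Of 14 genes linked to B cell activation, several of them also made by T or myeloid cells, 11 rose and 1 fell. In the GIMAP family of lymphocyte GTPases 7 of 8 fell and 1, Gimap5, rose. With total counts Gimap5 no longer passed, and with RLE scaling 6 fell.

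Transcripts of the T cell receptor chains moved apart. Of 19 tested TRBV (beta chain variable) genes 0 rose and 15 fell, and of 42 TRAV (alpha chain variable) genes 15 rose and 0 fell. With total counts 17 TRBV genes fell and 8 TRAV genes rose. The constant gene Trac rose by 0.72 ± 0.08 while Trbc1 (-0.68 ± 0.10) and Trbc2 (-0.94 ± 0.09), near-identical copies whose split is uncertain, fell. The effective number of TRBV genes was 14.1 to 14.5 in isograft and 13.9 to 14.2 in allograft libraries. No explanation was tested.

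For the number of changed genes, 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave 8632 genes by edgeR and was the 1 split with as many, and the highest of the others gave 0 (161 genes at an unadjusted p under 0.05, against 9206). Every other split puts libraries of both groups on each side, so the group difference widens the spread within sides. Few calls there were thus fixed in advance, and they are no measure of chance.

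The rise of the activation and costimulation list was set against 2 technical explanations. After removal of a smooth trend of length and GC its median was 2.28, against 2.29 before, and the list passed (adjusted p = 1.9e-11), which argues against that trend as the whole cause. More B-cell RNA in the allograft libraries would raise the B cell list too, and its median was -0.43. A response of T cells or of B cells to the allograft, and a difference in handling or culture between groups, stay open, since every library held RNA of both lineages and the labels give no batch.

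B-lineage transcripts may come from B cells left in the purified fraction, which CD3 selection is meant to remove. All 20 members of the B cell list were above 1 CPM in every library, with means of 880.9 CPM for Ighm and 285.5 for Igkc in isograft libraries. Of these genes Blk is also on the gamma delta and NKT list. A lower share of B cells as the whole difference between groups would lower its members alike, but 15 of 20 lay over 3 SE from the list's median, from Fcer2a (2.84) to Ralgps2 (-1.41). A change of state within B cells stays open, and the share of B cells cannot be read from these levels.

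The 6 members of the cell cycle list that rose, Tk1, Pcna, Mcm5, Mcm3, Mcm10 and Ccne2, act in DNA replication or its onset, but Mcm7 (-0.44), Ccne1 (-0.63) and Rrm2 (-0.36) of the same kind fell, as did mitotic genes such as Cenpf and Ccnb1. Replication genes of that list thus went both ways, and the hypothesis of a shift from G2 and M towards S phase was tested on genes outside it. The median log2 fold change of 32 S genes was above that of 32 G2/M genes by 0.46 (two-sided permutation p = 0.026 over genes, which are not independent replicates, 100000 permutations). The difference rested on the G2/M genes, with 18 down and 4 up (median -0.40), while 10 S genes rose and 7 fell (median 0.06). With total counts 6 S genes rose and 13 fell (median -0.17). Per library, the mean log2 level of S minus G2/M genes was higher in all 3 allograft than in all 3 isograft libraries, by 0.39 (exact permutation p = 0.1, the smallest that 3 against 3 can give). After removal of the length and GC trend the difference was 0.53, which argues against that trend as its cause. With a median of 0.06, the S genes alone do not show a shift towards S phase. Whether fewer G2/M transcripts in allograft libraries reflect cell cycle position, and in which cell type, stays open.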
